A study of Homo sapiens with 4 samples.

How the data were processed

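The series holds 4 poly(A) RNA-seq libraries of MCF10A cells. Per the labels' protocols, 0.35 x 1e6 cells were seeded the day before transfection with 50 nM siRNA and 4 uL of RNAiMAX in Opti-MEM, which was replaced by growth medium after 6 h, and cells were collected in TRIzol at 48 h. RNA was captured by its poly(A) tail and adapters were ligated, per the labels' protocols. The sequence of the siRNA against LMNA, and whether it was single or a pool, are not given in the sources used here. The genome build was hg38, per the submitters' processing notes; the aligner, the counter, the annotation and the use of strand are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart.

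The authors deposited 2 tables, each for 1 siLMNA and 1 siLacZ library of the same number, with 58051 gene identifiers. Per the file headers, each table gives raw read counts per gene in each library. Apart from the rows described below, the deposited normalized counts are a signal equal to the count times 1 factor per library, within each pair. Per the file headers the tables also hold a log2 fold change from the authors' comparison. A standard error and a test statistic, deposited beside it, were used as scores for checks of each row. The deposited p-values and adjusted p-values come from that comparison, which has no replicates. Of the columns in the table of pair 1, 3 have no name and were not used.

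Each row's columns were checked against each other, with a relative tolerance of 1e-06 and, for the fold change against the ratio of normalized values, a log2 tolerance of 0.05 above 20 reads. In 15 rows, of 8 genes, they did not match. For CDH1, TWIST1, ZEB1, CLDN1, OCLN and CCNB1 the count did not match the normalized value in at least 1 pair, and these 6 genes were left out of the library totals and of all tests except 1 added run and the check of each pair's table described below; they hold 0.0602% and 0.0623% of the deposited counts of siLacZ 1 and 2, and 0.447% and 0.273% of those of siLMNA 1 and 2. For CENPE and SNAI1 only the test columns did not match, and their counts were used. CCNB1 is listed more than once in the table of pair 1. As a further check, the fold change and its error were recomputed from the counts of each pair with DESeq2 (dispersion estimated without the group) for genes with at least 10 reads in both libraries. Of 16908 genes in pair 1, 6 differed from the deposited values by over 0.01 (log2) or 1% (error), and of 16885 in pair 2, 7 did. All were among the 8 genes, except TNC in pair 2, named here after its value was seen.

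Totals ranged from 42.8 to 46.2 (in units of 1e6 counts) per library, so that 3 counts, the limit a count of 0 allows, correspond to 0.0649 to 0.0701 CPM. Intervals and floors cover counting error only. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 9.39 in siLacZ and 7.10 in siLMNA). That difference cannot tell separate cultures from repeat libraries of the same culture. All 4 libraries were used as separate samples. Identifiers were matched to GENCODE 29, on the same build, for coordinates, transcript length and GC content, and 57447 of 58051 matched.

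The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts of all 4 libraries, with TMM factors, genes kept by filterByExpr, the group as the only term and Benjamini-Hochberg adjustment at 0.05. It tested 18540 genes, with a common biological coefficient of variation of 0.0655. CPM values are scaled by TMM, and the standard error of a log2 fold change is its size divided by the square root of the test's F. Before the data were examined, 33 gene lists were fixed, on the nuclear lamina and envelope, PRC2, Polycomb repressive complex 1 and H3K27 demethylases, Polycomb targets, epithelial junctions, mesenchymal markers, EMT transcription factors, TGF-beta, YAP and TAZ, keratins, cornified differentiation, hemidesmosomes and basement membrane, actin, DNA replication, mitosis, p53, the senescence secretory phenotype, interferon, NF-kappaB, antigen presentation, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein and integrated stress responses, immediate early genes, heat shock, RNA interference, histones, mitochondrial transcripts, ribosomal proteins, fibroblasts, endothelial cells, leukocytes and luminal breast cells. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1; log2 CPM with a prior count of 2, preset correlation 0.01). Of these, 18 passed at an adjusted p under 0.05. With the correlation estimated from the data, 0 passed, and fry was run as a further alternative. The run with an estimated correlation takes its degrees of freedom from the 4 libraries, not from the genes, so it has little power. For cholesterol synthesis the estimated correlation was -0.026, yet the unadjusted camera p went from 2.23e-13 to 0.0142. Not passing in that run therefore does not show that correlated genes account for a list's result. Fry's directional p asks whether the genes of a list move on balance one way, without setting them against other genes.

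The genes named in the results were set by a rule fixed before the data were examined: LMNA; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM and the same direction in both pairs; EZH2, SUZ12, EED, LMNB1, LMNB2, EMD, LBR, CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, ZEB2 and TWIST1; and up to 4 of the largest changes in each list. Pseudogenes and unnamed loci were counted but not named. Some genes that the rule selects are not reported. COL1A2, COL3A1 and the members of gene families chosen after the data were examined were named after their values were seen. The agreement of the pairs was described on log2(CPM + 1).

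Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, library size only, no low-count filter, a filter of 5 CPM in 2 libraries, limma-voom, a minimum fold change of 1.5 (glmTreat), an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. Added after the data were examined were runs with the 6 genes as deposited and without CENPE and SNAI1, and a test of the nuclear lamina list without LMNA. Tested on simulated data for siLMNA against siLacZ with 18019 genes and 200 of them changed, the edgeR test recovered 90% of genes changed by 1 and 100% of those changed by 2 on the log2 scale, with 9 false calls (4.52% of its calls). In a simulation in which the mesenchymal list was raised by 0.5 on the log2 scale, camera called that list and 1 of the others. The other list shares genes with it. Both simulations drew genes independently, whereas the correlation estimated from the data was 0.816 for the ribosomal protein list. They therefore do not test the preset correlation. In the data 54.3% of genes passed, far more than were changed in the simulation, so the share of false calls may differ. Tables were read with pandas 2.3.3 and drawn with matplotlib 3.10.9 under Python 3.11.15.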

Results

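Poly(A) RNA was sequenced from MCF10A, an established non-tumorigenic human mammary epithelial cell line, after transfection with an siRNA against LMNA or with a control siRNA against the bacterial gene LacZ. LMNA encodes lamins A and C, intermediate filament proteins of the nuclear lamina. The title of the series places the experiment in a study of lamin A/C, the Polycomb methyltransferase EZH2 and epithelial-to-mesenchymal transition (EMT). Each group had 2 libraries, named siLacZ 1 and 2 and siLMNA 1 and 2. Total counts, in units of 1e6, were 42.8 in siLacZ 1, 46.2 in siLacZ 2, 44.5 in siLMNA 1 and 44.2 in siLMNA 2. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

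The siRNA's target was lower in both siLMNA libraries. LMNA (ENSG00000160789; hg38 chromosome 1, 156082573 to 156140089, plus strand) was at 480 and 524 CPM in the control libraries and at 61.1 and 58.1 CPM in the siLMNA libraries. Its log2 fold change was -3.07 (SE 0.077, n = 2 per group), an 8.42-fold fall (edgeR adjusted p = 2.98e-15). Of 25 measured genes of the nuclear lamina and nuclear envelope, 15 fell, 4 rose and 6 did not pass the test, and 16 fell when adjusted over the list alone (camera adjusted p = 0.00226). With an estimated correlation, a run limited by the degrees of freedom of 4 libraries, the list did not pass (adjusted p = 0.460 with an estimated correlation). The list includes LMNA, the siRNA's own target; of the other 24 genes 14 fell, 4 rose and 6 did not pass, with 15 fallen when adjusted over those genes alone (camera adjusted p = 0.00740; adjusted p = 0.502 with an estimated correlation). LMNB1, which encodes lamin B1, fell from 100 ± 4.98 to 35.3 ± 1.60 CPM (SD, n = 2 per group; log2 fold change -1.51, SE 0.077). LBR, the lamin B receptor, had a log2 fold change of -0.92 (SE 0.069), and NUP210, a nuclear pore membrane protein, one of -1.35 (SE 0.082). LMNB2 (lamin B2) and EMD (emerin) fell by 0.70 (SE 0.072) and by 0.42 (SE 0.076) on the log2 scale. Against a minimum change of 1.5-fold, neither LMNB2 (adjusted p = 0.0803) nor EMD (adjusted p = 1.00) passed.

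Across the transcriptome, 4911 of 18540 tested genes rose and 5157 fell after LMNA siRNA (edgeR quasi-likelihood test, adjusted p under 0.05), which is 54.3% of the tested genes. Of those that passed, 2094 rose and 1326 fell by at least 2-fold, and 338 rose and 53 fell by at least 8-fold. The direction was the same in both same-numbered pairs for 10063 of the 10068 genes. These genes were called on the same 4 libraries, so this agreement is largely built into the call. Over all 18540 tested genes, 82.0% had the same sign in both pairs. Among genes that passed with a mean of at least 5 CPM, the highest fitted rise was that of C4orf26, with 2 control counts in all against 2822 in siLMNA, a ratio of 1514 with a 95% counting interval of 419 to 12509. It was followed by ITGB3, an integrin beta subunit (log2 fold change 8.73), and by POSTN, the matrix protein periostin, which went from 1.88 ± 0.818 to 464 ± 56.1 CPM (SD, n = 2 per group). MMP3 (a matrix metalloproteinase), ACKR3 (an atypical chemokine receptor), LBH (a transcription cofactor), AMTN (amelotin), TGM2 (transglutaminase 2) and SEMA7A (a semaphorin) had log2 fold changes of 7.87, 7.59, 7.45, 7.13, 7.05 and 6.83. Apart from LMNA, the largest falls at that level were those of SPRR1B (log2 fold change -4.62, SE 0.11), a cornified envelope precursor, FGFBP1 (-4.19, SE 0.089), a carrier of fibroblast growth factors, and KRT15 (-3.18, SE 0.085), a basal keratin. SULT1E1 (estrogen sulfotransferase), PLA2G4A (cytosolic phospholipase A2), NMU (neuromedin U), SLC16A5 (a monocarboxylate transporter family member), SPINK5 (a serine protease inhibitor) and TGM1 (transglutaminase 1) had log2 fold changes of -3.07, -3.02, -2.94, -2.90, -2.87 and -2.85. The sizes of 5 of these rises rest on 10 or fewer control counts. ITGB3 had 0 and 8 in the control libraries (ratio 439, 95% counting interval 223 to 1019), MMP3 had 0 and 6 (ratio 244, interval 112 to 667), ACKR3 had 4 and 2 (ratio 202, interval 92.3 to 550) and AMTN had 4 and 4 (ratio 145, interval 73.2 to 336). Without siLacZ 1 the log2 fold changes of C4orf26, ITGB3 and MMP3 were 9.50, 7.78 and 6.93. Without siLacZ 2 the control held 0 counts of each, and the fitted 13.49, 13.71 and 12.44 then depend on the prior count. With a minimum change of 1.5-fold as the null, 2111 genes rose and 1735 fell. Without siLacZ 2, 3182 rose and 3121 fell.

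Genes of the mesenchymal state rose together. Of the 50 genes on the mesenchymal list, 14 also stand on another list. Of 45 measured mesenchymal markers, 39 rose, 1 fell and 5 did not pass, with 40 risen when adjusted over the list alone (median log2 fold change 2.83; camera adjusted p = 4.05e-21; adjusted p = 0.349 with an estimated correlation). FN1, encoding fibronectin (ENSG00000115414; hg38 chromosome 2, minus strand), went from 204 ± 33.7 to 20972 ± 849 CPM (SD, n = 2 per group; log2 fold change 6.68, SE 0.11) and took 1.96% and 2.10% of the counts of the siLMNA libraries. CDH2, encoding N-cadherin, rose from 6.05 ± 0.806 to 91.8 ± 4.17 CPM (log2 fold change 3.92, SE 0.099). VIM, encoding the intermediate filament protein vimentin, rose from 69.2 ± 1.22 to 166 ± 3.79 CPM (log2 fold change 1.26, SE 0.070). Among 16 measured transcription factors that drive EMT, 10 rose, 1 fell and 5 did not pass (camera adjusted p = 0.000886; adjusted p = 0.403 with an estimated correlation). SNAI1 had a log2 fold change of 4.07 (SE 0.28; 4.70 without siLacZ 2), SOX4 of 2.94 (SE 0.073), ETS1 of 1.72 (SE 0.074) and SNAI2 of 1.24 (SE 0.074). ZEB2 was at 14.4 ± 0.0131 CPM in the control and 13.7 ± 1.97 CPM in siLMNA and did not pass (edgeR adjusted p = 0.611).

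CDH1, TWIST1 and ZEB1, genes widely used to score EMT, were not compared. The deposited counts and normalized values of CDH1 (E-cadherin), TWIST1 and ZEB1 (transcription factors) contradict each other in at least 1 pair, as do those of CLDN1, OCLN and CCNB1, and these 6 genes were left out of the tests given here. For TWIST1 the authors' deposited table of pair 1 lists 1218 control and 106550 siLMNA counts and a log2 fold change of 7.15, whereas its test statistic times its standard error gives -0.15. In the authors' deposited table of pair 2, TWIST1 has 1325 and 1021 counts, a fall, beside a positive log2 fold change. For CDH1 the authors' deposited tables list 14680 control and 2175 siLMNA counts in pair 1, and 16485 and 2413 counts in pair 2. The siLMNA count times the library's factor is 2221 and 2482, against normalized values of 2175 and 2412. For TWIST1 in pair 1 it is 108810 against 106549, a mismatch of the same kind. The normalized value over the count is 0.999994 for TWIST1 in pair 1, and 1.00005 and 0.999788 for CDH1. The library factors are 1.02121 in pair 1 and 1.02844 in pair 2. The authors' deposited log2 fold change of CDH1 is -2.69 in both pairs, and in pair 1 its test statistic times its standard error gives -7.26. For SNAI1, whose counts match its normalized values, the authors' deposited log2 fold change in pair 2 is 4.40, against 3.40 from the ratio of its normalized values; the rise given above uses the counts. For CDH1 the deposited counts, normalized values and fold changes all point down, but no test is given here for CDH1, TWIST1 or ZEB1. Of the other 47 epithelial adhesion and junction genes, 20 rose, 17 fell and 10 did not pass (camera adjusted p = 0.439; adjusted p = 0.848 with an estimated correlation). Members moved in opposite directions: CLDN4 (claudin 4) and CGN (cingulin), both of tight junctions, had log2 fold changes of 2.12 (SE 0.12) and 2.06 (SE 0.096), while PKP2 (plakophilin 2, of desmosomes) and LAD1 (ladinin 1) had -1.70 (SE 0.079) and -1.70 (SE 0.078).

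**Figure D1:**
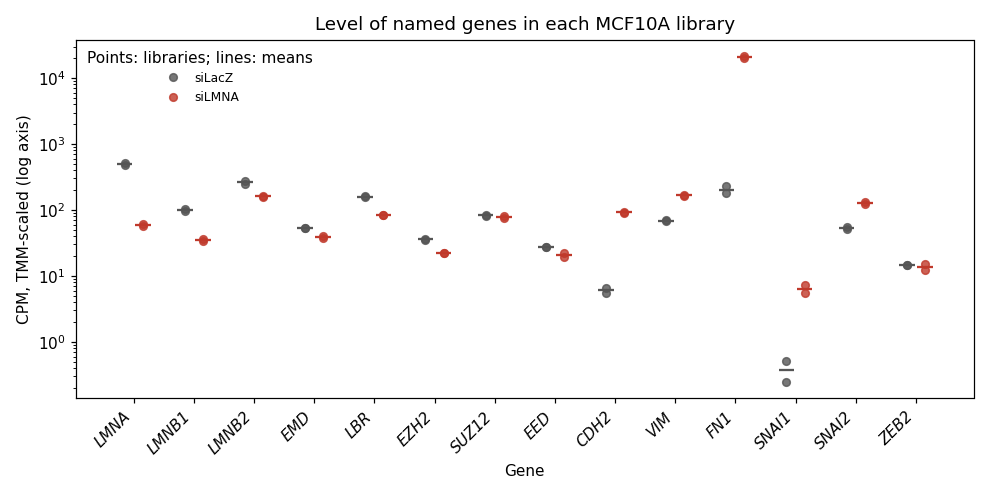
Level of each named gene in CPM, scaled by TMM, on a log axis, with a point per library (grey, siLacZ; red, siLMNA) and a line at the mean of the 2 libraries of a group. LMNA fell from 502 to 59.6 CPM and FN1 rose from 204 to 20972 CPM on average, while the points of SUZ12 and ZEB2 overlap or nearly meet between the groups.

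EZH2 was lower after LMNA siRNA. EZH2 (ENSG00000106462; hg38 chromosome 7, minus strand), the catalytic subunit of Polycomb repressive complex 2 (PRC2), went from 35.7 ± 1.49 to 22.1 ± 0.110 CPM (SD, n = 2 per group; log2 fold change -0.69, SE 0.084; edgeR adjusted p = 1.71e-06). EED, another core subunit, fell by 0.40 (SE 0.094) on the log2 scale, and SUZ12 did not pass (log2 fold change -0.08, SE 0.074; edgeR adjusted p = 0.409). Against a minimum change of 1.5-fold, EZH2 did not pass (adjusted p = 0.135), nor did EED (adjusted p = 1.00), and the call on EED was lost without siLacZ 1 (adjusted p = 0.0944) or without siLacZ 2 (adjusted p = 0.119). Over the 13 measured PRC2 genes 4 rose, 6 fell and 3 did not pass (camera adjusted p = 0.352). The accessory subunits PHF19 (log2 fold change -1.49, SE 0.081) and JARID2 (0.84, SE 0.074) moved apart. Of 20 genes of Polycomb repressive complex 1 and the H3K27 demethylases, 10 rose, 4 fell and 6 did not pass (camera adjusted p = 0.152), with KDM6B, a demethylase, at a log2 fold change of 0.84 (SE 0.078). The list of developmental regulators that are textbook Polycomb targets holds 90 genes, of which 45 had too few counts to be tested. Of the 45 measured targets, 6 rose, 11 fell and 28 did not pass (camera adjusted p = 0.857). Their median log2 fold change was 0.04, while the mean was -0.02 and the test pointed down. TBX3 rose (log2 fold change 1.46, SE 0.10) and IRX3 fell (-1.67, SE 0.081).

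Genes of transforming growth factor beta (TGF-beta) signalling, of YAP and TAZ, of the actin cytoskeleton and of the basement membrane rose. The lists are not all independent: 8 of 32 TGF-beta genes and 6 of 26 YAP and TAZ genes also stand on another list. TGFB2 and CTGF stand on both. In the TGF-beta list 24 of 31 genes rose, 5 fell and 2 did not pass (camera adjusted p = 6.85e-09; adjusted p = 0.349 with an estimated correlation). The ligands INHBA and TGFB2 had log2 fold changes of 3.87 (SE 0.087) and 4.11 (SE 0.18). Of 26 YAP and TAZ response genes 21 rose, 1 fell and 4 did not pass (camera adjusted p = 4.80e-09; adjusted p = 0.374 with an estimated correlation), with CTGF at 4.36 (SE 0.12) and CYR61 at 3.29 (SE 0.085). Of 35 actomyosin and focal adhesion genes 26 rose, 2 fell and 7 did not pass, with 27 risen when adjusted over the list alone (camera adjusted p = 1.33e-10; adjusted p = 0.349 with an estimated correlation). MYL9, a myosin light chain, and TPM1, a tropomyosin, had log2 fold changes of 3.57 (SE 0.080) and 2.89 (SE 0.071). Of 25 hemidesmosome and basement membrane genes 20 rose, 1 fell and 4 did not pass (camera adjusted p = 1.54e-08; adjusted p = 0.374 with an estimated correlation). COL4A1, a collagen IV chain, had a log2 fold change of 3.58 (SE 0.074).

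Keratins and squamous differentiation genes moved in both directions. Of 17 keratins 7 rose, 6 fell and 4 did not pass (camera adjusted p = 0.499), and their median log2 fold change of 0.10 and mean of -0.01 differ in sign. KRT17 went from 1698 to 6795 CPM (log2 fold change 2.00, SE 0.071) and KRT6B had a log2 fold change of 1.71 (SE 0.080), both uncertain because near-identical copies can share their reads. Of 31 squamous differentiation genes 7 rose, 14 fell and 10 did not pass (camera adjusted p = 0.0632). Among other alternatives, the list passed, toward lower, with DESeq2 (adjusted p = 0.00296), upper-quartile factors (0.0432), no low-count filter (0.0399), fry (0.00844) and without siLMNA 1 (0.0472), in a range from 0.00296 to 0.512 over its alternatives, the highest with an estimated correlation. Besides SPRR1B and TGM1, which fell, IVL (involucrin, a cornified envelope protein) rose (log2 fold change 2.82, SE 0.12).

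All measured genes of DNA replication and of mitosis in the lists fell. Of 45 DNA replication and E2F target genes, 45 fell (median log2 fold change -1.37; camera adjusted p = 8.70e-22; adjusted p = 0.349 with an estimated correlation), among them MCM6, a subunit of the replicative helicase (-1.93, SE 0.084), and the licensing factor CDT1 (-1.85, SE 0.095). Of 44 genes of G2 and mitosis, 44 fell (median log2 fold change -1.73; camera adjusted p = 1.16e-24; adjusted p = 0.349 with an estimated correlation). MKI67, which encodes the proliferation marker Ki-67, went from 474 to 109 CPM (log2 fold change -2.12, SE 0.12), and HMMR had a log2 fold change of -2.67 (SE 0.096). CCNB1, encoding cyclin B1, is one of the genes left out. Of 30 direct p53 targets 19 rose, 3 fell and 8 did not pass (camera adjusted p = 0.000107; adjusted p = 0.403 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, went from 203 to 582 CPM (log2 fold change 1.52, SE 0.076), and TP53INP1 had a log2 fold change of 1.79 (SE 0.078). Of 17 replication-dependent histone genes, whose main transcripts lack a poly(A) tail, 11 rose, 1 fell and 5 did not pass, with 2 fallen when adjusted over the list alone (camera adjusted p = 0.00497; adjusted p = 0.403 with an estimated correlation). HIST1H1C had a log2 fold change of 2.00 (SE 0.11); reads of these genes can be shared between near-identical copies.

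Of 34 secreted factors of the senescence-associated secretory phenotype 29 rose and 5 fell (camera adjusted p = 1.16e-12; adjusted p = 0.349 with an estimated correlation). IL6 had 0 counts in the control libraries and 688 in the siLMNA libraries, at least 246-fold higher against a floor of 3 counts over the control group. MMP1 had 2 control and 122 siLMNA counts, a ratio of 65.5 with a 95% counting interval of 17.7 to 547. Both control counts were in siLacZ 1: the fitted log2 fold change of 5.86 was 4.92 without siLacZ 2, and 8.98 without siLacZ 1, where the control held 0 counts and the fit depends on the prior count. MMP10 had 4 and 6 control counts and 575 siLMNA counts, a ratio of 61.7 (95% counting interval 33.3 to 129). Of 25 NF-kappaB response genes 21 rose, 0 fell and 4 did not pass (camera adjusted p = 4.38e-12; adjusted p = 0.349 with an estimated correlation). The chemokine gene CXCL8 and the adhesion receptor gene ICAM1 had log2 fold changes of 2.40 (SE 0.084) and 2.13 (SE 0.082). The secretory and NF-kappaB lists are not independent: 11 of 37 and 8 of 25 of their genes also stand on another list. IL6 stands on both. Of 18 MHC class I antigen presentation genes 12 rose, 2 fell and 4 did not pass, with 13 risen when adjusted over the list alone (camera adjusted p = 0.000886; adjusted p = 0.438 with an estimated correlation). HLA-B had a log2 fold change of 2.07 (SE 0.086), uncertain because HLA genes share reads, and TAPBP, which loads peptides, had 1.20 (SE 0.071). Of 42 interferon-stimulated genes 16 rose, 11 fell and 15 did not pass, with 17 risen when adjusted over the list alone (camera adjusted p = 0.374). IFI6 rose (log2 fold change 1.47, SE 0.096) and OAS1 fell (-1.45, SE 0.12).

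Ribosomal protein and cholesterol synthesis genes fell. All 72 measured cytosolic ribosomal protein genes fell, by a median log2 fold change of -0.72 (camera adjusted p = 2.33e-23; adjusted p = 0.403 with an estimated correlation), among them RPL14 (-1.33, SE 0.067) and RPSA (-1.15, SE 0.064). Their processed pseudogenes can share reads with them. Of 29 cholesterol synthesis and SREBP2 target genes 28 fell and 1 did not pass (camera adjusted p = 1.19e-12; adjusted p = 0.349 with an estimated correlation), with SCD, stearoyl-CoA desaturase, going from 1881 to 557 CPM (log2 fold change -1.76, SE 0.072) and ACAT2 at -1.40 (SE 0.074). Of 31 genes of the unfolded protein and integrated stress responses 18 rose, 7 fell and 6 did not pass (camera adjusted p = 0.0112; adjusted p = 0.349 with an estimated correlation), and the list did not pass with DESeq2 (adjusted p = 0.0517) or at a threshold of 0.01, in a range from 0.000244 to 0.349 over its alternatives. ATF3, a stress-induced transcription factor, rose (log2 fold change 2.60, SE 0.17), while PHGDH and SLC7A11, of serine synthesis and cystine import, fell (-1.77, SE 0.16, and -1.72, SE 0.13). Glycolysis and hypoxia genes went both ways, with 19 of 39 risen, 9 fallen and 11 not past, and 10 fallen when adjusted over the list alone (camera adjusted p = 0.0660). The list passed with upper-quartile factors (adjusted p = 0.0439), fry (0.0209) and without siLMNA 2 (0.0327), in a range from 0.0209 to 0.551 over its alternatives. ENO2, the neuronal enolase gene, rose (log2 fold change 1.62, SE 0.20) and the carbonic anhydrase gene CA9 fell (-2.30, SE 0.13). Of 30 immediate early genes 16 rose, 9 fell and 5 did not pass (camera adjusted p = 0.0632), with JUN at 2.28 (SE 0.079) and EGR1 at -1.96 (SE 0.080). Among other alternatives, that list passed, toward higher, with DESeq2 (adjusted p = 0.0119), library size only (0.0461), fry (0.0209) and without siLMNA 2 (0.0390), in a range from 0.0119 to 0.551 over its alternatives. Of 17 heat shock genes, cytosolic and mitochondrial, 5 rose, 8 fell and 4 did not pass (camera adjusted p = 0.439), with CRYAB, a small heat shock protein, at 3.64 (SE 0.15) and HSPE1 at -1.10 (SE 0.080); the list's median of -0.15 and mean of 0.07 differ in sign. Of 13 genes of the RNA interference machinery 3 rose, 4 fell and 6 did not pass (camera adjusted p = 0.857), with AGO4 at 1.70 (SE 0.095); the median of -0.02 and the mean of 0.11 differ in sign. Of 13 transcripts of the mitochondrial genome 4 fell and 9 did not pass (camera adjusted p = 0.451). The list's call depends on the control library: adjusted p = 0.0151 without siLacZ 1, and adjusted p = 0.646 with the direction turned (median log2 fold change 0.08) without siLacZ 2, in a range up to 0.921 over its alternatives. Without siLacZ 2 none of the 4 passed (adjusted p from 0.0549 for MT-ATP8 to 0.163 for MT-CO2), and MT-ATP8 did not pass without siLacZ 1 (0.100) or siLMNA 2 (0.0516). MT-ATP6 did not pass with DESeq2 (adjusted p = 0.0529), and none of the 4 passed against a minimum change of 1.5-fold (adjusted p = 1.00 for each).

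**Figure D2:**
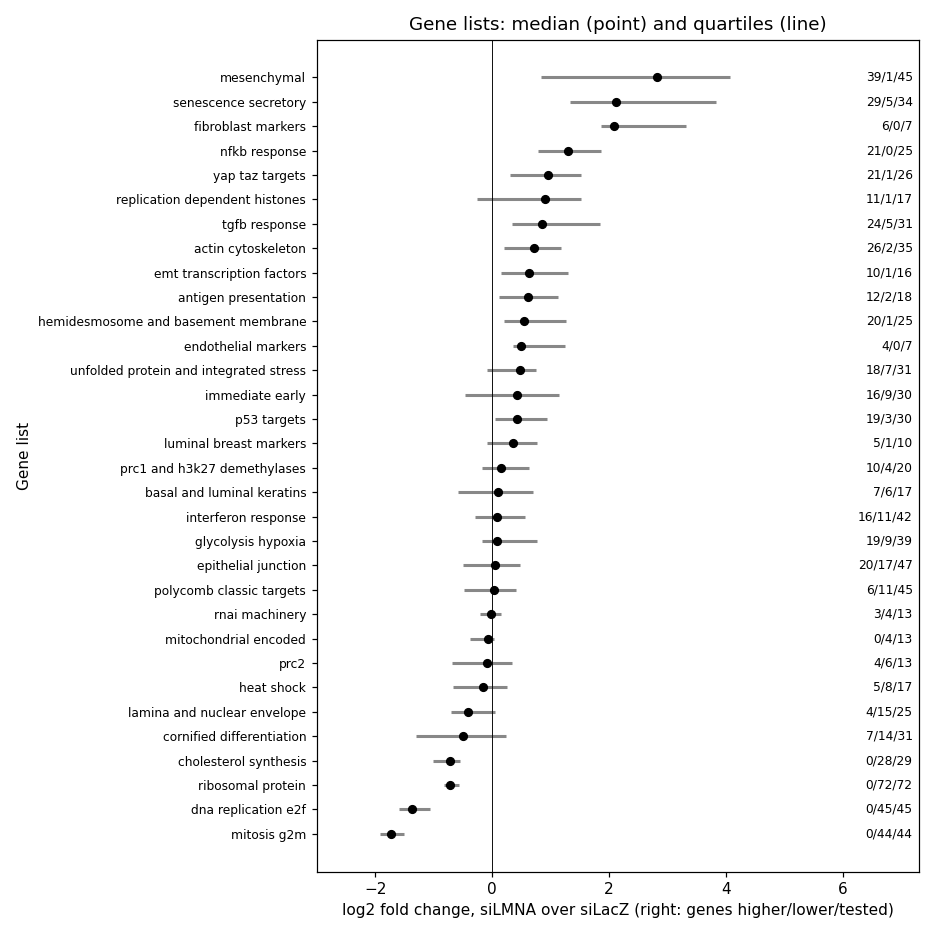
Log2 fold change of siLMNA over siLacZ (x axis) in each gene list (y axis), with a point at the median of the list's tested genes and a line between the quartiles. The numbers at the right give the genes that rose, that fell and that were tested. The mesenchymal list has the highest median (2.83) and the mitosis list the lowest (-1.73); 6 lists with a median near 0 change the sign of that median with the scaling.

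Markers of other cell types were measured beside these groups. Of 7 measured fibroblast markers 6 rose and 1 did not pass (camera adjusted p = 9.91e-05; adjusted p = 0.349 with an estimated correlation), with FAP at a log2 fold change of 3.35 (SE 0.093) and COL1A1 at 3.29 (SE 0.082). Of the 12 genes on that list, 9 also stand on another list, and 5 had a mean of at least 1 CPM in the control. COL1A2, an abundant fibroblast collagen, had 0 counts in each control library and 10 and 20 counts in the siLMNA libraries, and COL3A1 had 0 counts in all 4 libraries. Of 7 endothelial markers 4 rose and 3 did not pass (camera adjusted p = 0.0739), with EGFL7 at 1.46 (SE 0.19) and ROBO4 at 1.05 (SE 0.13). That list passed with no low-count filter (adjusted p = 0.00723), fry (0.0209) and without siLacZ 2 (0.00883), in a range from 0.00723 to 0.403 over its alternatives. Of 10 luminal breast markers 5 rose, 1 fell and 4 did not pass (camera adjusted p = 0.127), with KRT8 at 1.19 (SE 0.068). Only 2 of 12 leukocyte markers were measured well enough to be tested, too few for a list test. For every list whose 2 kinds of count are not given separately, the counts adjusted over the list alone equalled those over all genes.

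The deposited tables compare 1 siLMNA with 1 siLacZ library each. Across 18540 genes, which are not independent replicates, the log2 differences of the 2 same-numbered pairs had a Pearson r of 0.926 and a Spearman rho of 0.857, and 82.0% had the same sign. At an adjusted p under 0.05, 0 genes passed in either pair of the authors' deposited tables, against 10068 genes with edgeR on all 4 libraries, and 4414 higher and 4429 lower with DESeq2. The smallest adjusted p in the authors' deposited table of pair 1 was 0.0951, for FN1, and in that of pair 2 it was 0.997. At an unadjusted p under 0.05, the authors' deposited tables hold 518 genes higher and 164 lower in pair 1, and 475 higher and 184 lower in pair 2. Of these, 391 were higher and 110 lower in both, where independent lists would share 9.11 and 1.12, and all of them also passed in the same direction in the test on 4 libraries. The test on 4 libraries used the same counts as the 2 tables, so its calls are no independent check of that overlap. Tests on the reads of 2 libraries compare those libraries, not the conditions.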

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

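Of the tests in this part, those on the rows whose columns contradict each other and on fibroblast transcripts were chosen after their result was seen.

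Of the counts left out of the comparisons, some lie above the control and others below it. In the deposited tables the siLMNA count of TWIST1 in pair 1 is 106550 (control 1218), that of ZEB1 is 14630 in pair 1 (control 158) and 639 in pair 2 (control 134), and that of CCNB1 is 75962 in pair 1 (control 6077) and 116702 in pair 2 (control 6785). Those of OCLN (47 and 61, controls 730 and 792), CLDN1 (377 and 426, controls 2938 and 3284) and CDH1 (2175 and 2413, controls 14680 and 16485) lie below, as does TWIST1 in pair 2 (1021, control 1325). Except the last, they stand among 12 rows in which the siLMNA count does not match the normalized value, and 5 of the 15 rows with any contradiction break the order of the table, which is sorted by log2 fold change. For TWIST1 in pair 1 the neighbouring rows hold -0.15 on both sides, while the row lists 7.15. The row of CCNB1 out of order in pair 1 stands between rows at -1.91, and its statistic times its error gives -1.91, a siLMNA count of 1550. That of ZEB1 in pair 1 stands between rows at 1.61, and its statistic times its error gives 1.61, a count of 463.

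A chance draw of 8 genes from the 18546 measured does not account for which rows are concerned: 6 of the 8 belong to the lists on epithelial junctions, mesenchymal markers and EMT transcription factors, where 0.0487 would be expected (exact hypergeometric test, p = 1.24e-12). Normalized values copied into the count column account for part at most: 9 of the 12 rows have a normalized value within 1 of the count, and the others do not. How the values came to differ stays open, and no biological explanation was tested. The counts of the 6 genes left out enter none of the tests given in the results, only the added run with them as deposited and the check of each pair's table.

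The mesenchymal list rose by a median log2 fold change of 2.83, together with fibroblast markers. Fibroblasts in the siLMNA cultures would bring COL1A2 and COL3A1, but the higher of the pair was at 0.00167% of the level of FN1 in siLMNA. With the trend on GC content and transcript length removed from each library, the list's median was 2.64, against 2.63 before on the same log2 CPM scale (camera adjusted p = 3.32e-21 after), although the correction moved the log2 fold changes of genes by a median of 0.0936. A response to the LMNA siRNA therefore remains as a hypothesis, found and tested on the same data. An effect of the siRNA on other transcripts stays open, since the sources used here name no further siRNA against LMNA.

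The fall of all 72 ribosomal protein genes (median log2 fold change -0.72) was set against technical trends in the same way. With the trend on GC content and length removed the median was -0.62 (camera adjusted p = 5.99e-22). A few abundant genes took more of the counts in siLMNA, where the top 10 genes held 10.1% and 9.99% against 5.50% and 5.54% in the control. Of 10000 random lists matched on mean CPM, the lowest median was -0.35 and the middle one 0.04. These lists cannot test that explanation, because TMM scaling had already removed a shift common to all genes. They were also drawn gene by gene, whereas the estimated correlation of the ribosomal protein list was 0.816, so their range is too narrow. With library size only, which leaves such a shift in, the median was -0.82 for the ribosomal protein list and -0.11 for all genes. A shift common to all genes would thus account for little of the fall. Slower growth of the siLMNA cultures, with the fall of DNA replication and mitosis genes beside it, may be a candidate explanation, and it was not tested.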

How the results depend on the processing

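The alternatives were planned, except the lamina list without LMNA and the runs with the 6 left-out genes as deposited (4897 genes higher, 5156 lower) and without CENPE and SNAI1 (4911 and 5157). The counts of 4911 and 5157 stayed within 1.5 times in all runs except with a minimum fold change of 1.5 (2111 higher, 1735 lower), which tests a larger change, and without siLacZ 2. Over the libraries left out in turn they ranged from 3182 to 4283 higher and from 3121 to 4696 lower, the lowest without siLacZ 2; fewer samples were tested, and the lone library of a group was assumed to vary like the others. With DESeq2 4414 rose and 4429 fell, with upper-quartile factors 5518 and 4575, and with library size only 4121 and 6065. The last moved the median of all genes from -0.01 to -0.11 on the log2 scale, and 40.5% of calls were then higher, against 48.8%. No gene past the threshold in the main test was called in the opposite direction in any run. LMNA stayed lower and past the threshold in all.

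No label says what a shared number means, so the main test used no replicate block. Same-numbered libraries also did not deviate together (correlation of deviations -0.066 across genes). Same-numbered pairs were used only to describe agreement, in the rule for naming genes and in the test on gene surroundings. With the replicate block 4870 genes rose and 5093 fell.

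Of 2281 values of 144 other genes, 2209 kept their direction and side of the threshold, 71 kept the direction but no longer passed, and 1 reversed: ZEB2, which did not pass, had log2 fold changes from -0.23 (without siLMNA 2) to 0.0633 (without siLMNA 1) with a library left out. Of 543 list values, 495 stayed as they were, 21 no longer passed (18 of them with an estimated correlation), 22 newly passed (squamous differentiation 6, immediate early 5, glycolysis 3, endothelial 3, mitochondrial transcripts 1, and with fry alone PRC2, Polycomb repressive complex 1, heat shock and luminal) and 5 reversed, all in lists that did not pass. The reversed adjusted p-values were, for RNA interference, 0.894 with library size only, 0.994 without a filter and 0.970 without siLacZ 1 (with a library left out, from 0.671 to 0.980), for Polycomb targets 0.871 with a filter of 5 CPM, and for mitochondrial transcripts 0.646 without siLacZ 2 (from 0.0151, without siLacZ 1, to 0.921). The cause was not tested. The unfolded protein list no longer passed with DESeq2 (0.0517), with the block (0.0903) or at 0.01. With the block the squamous differentiation list (0.00630) and the immediate early list (0.0181) passed. The agreement of the pairs had an r of 0.841 with a pseudocount of 0.1, 0.957 with 5 and 0.935 crossed. For the authors' deposited tables, the alternatives of 0.01 and of a minimum log2 fold change of 1 are stricter than the limit used above. They could not change the count of 0 genes and say nothing on how firm it is. Below about 3 counts over a group only bounds or wide intervals can be given.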

Other observations

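After the data were examined, 12 gene families were chosen by symbol and tested with camera (the symbol patterns for integrins, initiation factors, tubulins and S100 proteins were narrowed after a first look, to drop genes that are not members); none passed with an estimated correlation (adjusted p from 0.138 to 0.758 with an estimated correlation). Of 27 collagen chains 19 rose and 0 fell (camera adjusted p = 1.39e-09), with COL6A2 at a log2 fold change of 4.15 (SE 0.20) and COL8A1 at 2.14 (SE 0.071). Of 17 matrix metalloproteinases 14 rose and 1 fell (camera adjusted p = 3.40e-06), with the gelatinase genes MMP9 at 6.13 (SE 0.11) and MMP2 at 4.30 (SE 0.14). Of 20 integrin subunits 14 rose and 3 fell (camera adjusted p = 7.46e-05): ITGB6 had a log2 fold change of 3.36 (SE 0.072) and ITGAV, its alpha partner, one of 2.50 (SE 0.073), while ITGA4 fell (-2.20, SE 0.26). Of 10 laminin chains 8 rose and 0 fell (camera adjusted p = 0.000185), and of 17 semaphorins 10 rose and 4 fell (camera adjusted p = 0.0144).

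Of 78 mitochondrial ribosomal proteins 69 fell and 0 rose (camera adjusted p = 2.38e-16), with MRPS33 at -1.64 (SE 0.098) and MRPL3 at -1.13 (SE 0.072). Of 45 translation initiation factors 31 fell and 2 rose (camera adjusted p = 1.19e-06), with EIF2B5, a subunit of a nucleotide exchange factor, at -1.26 (SE 0.076). Of 18 aminoacyl-tRNA synthetases 14 fell and 0 rose (camera adjusted p = 7.34e-06), and of 37 proteasome subunits and assembly factors 25 fell and 3 rose (camera adjusted p = 0.000157). Of 16 S100 proteins 10 fell and 2 rose (camera adjusted p = 0.00366). Tubulins (4 of 17 higher, 5 lower; camera adjusted p = 0.617) and desmosomal proteins (6 of 10 higher, 3 lower; camera adjusted p = 0.390) did not pass.

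A hypothesis from the place of lamins at the nuclear edge, that genes in gene-poor surroundings rise relative to genes in gene-dense ones after LMNA siRNA, was tested on 13760 protein-coding genes. The prediction, written before the result was seen, was a difference of at least 0.1 in both pairs between the genes with at most 13 and those with at least 42 protein-coding genes within 1 Mb on either side. With the trends on GC content, length and mean level removed, the difference in median log2 change was 0.02 in pair 1 and 0.00500 in pair 2, as small as between the libraries of a group (0.02 in siLacZ and 0.00483 in siLMNA). Before that removal it was -0.09 in pair 1 and 0.01 in pair 2. Between the libraries of a group (2 minus 1) it was then -0.01 in siLacZ and 0.09 in siLMNA. No such difference was detected in either form. Without the removal, the siLMNA libraries alone differed by nearly the 0.1 sought, so that form cannot decide the question.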
